A study of Mus musculus with 3 samples.

How the data were processed

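The 3 samples were 1 array each of parental WR19L cells, of DKO cells with wild-type human ATP11A and of DKO cells with Q84E ATP11A, and the groups were taken from the genotype in the labels for the first 2 and from the title for the Q84E array. Per the labels' protocols, cells were grown in RPMI1640 with fetal calf serum and left untreated, and biotinylated cRNA was made from 250 ng of total RNA with a 3' in vitro transcription kit. The deposited values are array intensity on a linear scale, a signal for each probe set, computed by the authors with MAS5 per the submitters' processing notes; its version, the scanner and its settings are not given in the sources used here. The deposited values of the 45101 probe sets had a trimmed mean, leaving out 2% at each end, of 500.0 on every array, so the arrays had been scaled to a common mean, and that scaling was kept. MAS5 scales each array by a single factor, so a shift of many genes in 1 direction can be partly removed or spread over the other genes. Detection calls were not used here, and low signals were handled by a floor instead.

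Gene names came from a table of the platform's annotation. Of the probe sets, 34958 had exactly 1 gene symbol, 932 had several and were not named, and 9211 were not listed in that table and stayed unnamed here. The 64 control probe sets fall within these classes, and any with exactly 1 gene symbol were not left out of the comparisons. Of the named ones 34754 were matched to RefSeq genes of assembly GRCm38.p6 by their Entrez identifier, and 0 of the symbols had changed. RefSeq was used only for names and for which genes neighbour each other. No genome build is given in the sources used here, so no coordinates are printed.

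From the deposited signals, log2 levels were taken, and each gene of 18194 was represented by the probe set with the highest mean over the 3 arrays. A gene was compared if its level reached the 50th percentile of all probe sets on at least 1 array, which 11596 genes did. Levels under that percentile of their own array, a signal of 50.3 for parental, 50.5 for wild-type ATP11A and 55.5 for Q84E cells, were set to it before ratios were taken. A ratio of a level above both floors against a level under its own floor is a lower bound and is printed as "at least" or as a bound. Where both levels lay under the floor, in 401 genes for Q84E over wild-type, 392 for wild-type over parental and 367 for Q84E over parental, the ratio is only the difference between the floors, 0.14, 0.0057 and 0.14 on the log2 scale, and measures nothing. In a further 179, 8 and 190 genes a single level lay under the floor and the floor set the sign of the ratio. These genes stayed in the comparisons and lists. A ratio is the difference of 2 log2 levels. Genes were counted by size alone, at least 2-fold, for Q84E over wild-type, wild-type over parental and Q84E over parental, and for each array against both others. With 1 array per group no test between groups, SD or p-value could be had.

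The technical error was estimated from genes with at least 2 probe sets of similar level, all above the floor on all 3 arrays. It is the SD of the difference between the log2 ratios of 2 probe sets of a gene, scaled to 1 probe set. In 100 simulations, that error gave the counts for unchanged genes. These counts can be too low for genes near or under the floor, where the error was not estimated. Hybridisation controls had an SD of the log2 ratio of 0.063 to 0.093 over 18 probe sets, and Bacillus labelling controls of 0.20 to 0.27 over 24. The steps were tested on simulated data for Q84E over wild-type with 10943 genes in the step. Of genes changed 1.5-fold, 2-fold, 3-fold and 4-fold, 50 of each, 0%, 54%, 100% and 100% were called at least 2-fold. In the same data 26 unchanged genes were called. The changed genes were drawn from those with a mean level at or above the 75th percentile, so these shares need not hold for dimmer genes. Of the genes counted for Q84E over wild-type, 25 of 119 higher and 8 of 37 lower reached that percentile on the brighter array. Of 60 unchanged lists of 20 genes picked at random, 3.33% lay outside the central 95%, and lists shifted by 0.2 on the log2 scale were found in 100% of cases. Lists of genes that vary together were not simulated.

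A total of 36 gene lists with 713 symbols, of which 650 had a named probe set, were fixed, and 35 had at least 5 compared members. Each list's median log2 ratio was placed as a percentile among 10000 random lists of the same size matched on mean level in 20 bins, which describes these arrays and tests nothing across cultures. The named genes followed a rule. Atp11a and Tmem30a were always included, and a further item of the rule is not reported here. Per comparison, the 12 highest and 12 lowest genes were taken among those whose level on the brighter array reached the 75th percentile and whose other probe sets past the filter all had the same sign. Up to 4 members with the largest ratio were taken per list, and for each array the 5 highest and 5 lowest genes against both others, by the smaller of the 2 ratios and among genes that reached the 75th percentile in both comparisons of that array. The groups, comparisons, filter, floor, lists, rule for named genes and most alternatives were chosen before the data were examined. The reporting of lists outside the central 95% was not part of that plan.

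Alternatives were quantile normalization, a common median, floors at the 40th and 65th percentile or none, the mean of a gene's probe sets, leaving out probe sets with names ending in _x_at or _s_at, which can bind related transcripts, limits of 1.5-fold and 3-fold, the mean of a list and random lists without matching on level. A common floor for the 3 arrays, genes above the floor on both arrays compared, and the tests on neighbouring genes and on a list of FOXO targets were added after seeing the data. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.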

Results

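Gene expression was measured in a mouse T-lymphoma cell line, WR19L, which was derived from BALB/c mice. Total RNA from 3 kinds of cells was hybridised to Affymetrix microarrays, with 1 array per group. The first array held parental WR19L cells. The second held DKO cells, a flippase-deficient derivative of WR19L, that stably expressed wild-type human ATP11A. The third held DKO cells that expressed the Q84E mutant of ATP11A. ATP11A is a P4-ATPase, a flippase that moves phospholipids from the outer to the inner leaflet of the plasma membrane. DKO cells without a transgene belong to the series design and were not analysed here, so in every ratio over parental cells the effects of the knockout, of the transgene and of the derivation of the line cannot be separated. Each array gave a signal for 45101 probe sets, and the 75th percentile of the signal was 369 on the parental array, 373 on the wild-type ATP11A array and 392 on the Q84E array. With 1 array per group no value below has a replicate, no test across arrays was possible, and no p-value is given, so the number of arrays limits the precision. The measurement error was described by how far 2 probe sets of the same gene differed in their log2 ratio between arrays. As an SD scaled to 1 probe set, it was 0.31 to 0.35 for genes between the 50th and 75th percentile of signal. Between the 75th and 90th it was 0.17 to 0.19, and above the 90th 0.096 to 0.11. Differences between cultures of 1 line are not covered by that error. Values of named genes come from the brightest probe set, and of 235 such values with several probe sets past the filter, over the 3 comparisons, 82 had a probe set more than 1.5-fold away, bounds included. Across the 11596 genes compared, Pearson's r between arrays was 0.964 to 0.969, taken across genes, which are not independent replicates.

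The endogenous flippase gene was examined first. The signal of the brighter Atp11a probe set was 478 in parental cells, 253 in DKO cells with wild-type ATP11A and 244 in DKO cells with Q84E ATP11A. The dimmer Atp11a probe set gave 131 in parental cells and lay under the floor in both DKO lines. The log2 ratio of Atp11a was -0.92 for wild-type ATP11A cells over parental cells, -0.97 for Q84E cells over parental cells and -0.051 for Q84E over wild-type cells. These mouse probe sets may lie outside an edited site and need not detect a human transgene, so they check neither the edit nor the level of the transgene. Tmem30a encodes the chaperone subunit of most P4-ATPases, and its signal was 1292, 1567 and 1657 in parental, wild-type ATP11A and Q84E cells, while its 5 probe sets ranged from -1.10 to 0.42 in log2 ratio for Q84E over parental. Atp11b had signals of 1718, 1498 and 1764.

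The comparison of Q84E with wild-type ATP11A cells addressed how expression of the mutant protein, instead of the normal one, goes with gene expression in the same flippase-deficient background. The gene furthest apart was Sgms1, which encodes sphingomyelin synthase 1, the enzyme of the Golgi that makes sphingomyelin from ceramide and phosphatidylcholine. Its signal was 157 with wild-type ATP11A and 1977 with Q84E ATP11A, a 12.6-fold higher level, against 113 in parental cells. At least 2-fold higher levels with Q84E were found for 119 of the 11596 genes and at least 2-fold lower levels for 37. In simulations of unchanged genes with the probe set error, 27.6 genes on average and at most 41 in 100 simulations passed the same limit. With quantile normalization the split was 68 higher and 64 lower, and with a common median it was 92 higher and 43 lower, so whether higher genes were clearly in excess depended on the scaling. Of the 119 genes, 34 had a level under the floor on the wild-type array, as 12 of the 37 had on the Q84E array, and their ratios are lower bounds.

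After Sgms1, the highest ratios of Q84E over wild-type, among genes above the brightness limit, belonged to Glcci1, at 5.42-fold, and Avil, which encodes the actin-binding protein advillin, at 4.37-fold. Drc1, a component of the dynein regulatory complex of cilia, was 3.98-fold higher. Hemgn, a nuclear protein of blood cell precursors, was 3.63-fold higher, and Ndrg1, a gene induced by hypoxia and differentiation, was 3.59-fold higher, with all 5 of its probe sets past 2-fold. Iqce was 3.43-fold higher, P2rx3, an ATP-gated cation channel, 3.38-fold, and Plpp3, a phosphatase that removes phosphate from lipids such as lysophosphatidic acid, 3.14-fold. Ccng2, a cyclin G that is linked to cell cycle arrest, was 2.89-fold higher, Gimap8, a GTPase of lymphocytes, 2.81-fold, and Ddit4, an inhibitor of mTORC1 signalling, 2.65-fold. The Iqce value rested on 1 of 3 probe sets past 2-fold, and the other probe set of Glcci1 had a log2 ratio of 1.44. On the lower side, Rhox5, an X-linked homeobox gene, was 6.93-fold lower with Q84E than with wild-type ATP11A, at signals of 266 and 1845. Cyp2c55, a cytochrome P450, was 5.40-fold lower, Slc6a13, a GABA transporter, 3.67-fold, and Sohlh1, a germ cell transcription factor, 2.99-fold. Trat1, an adaptor that associates with the T cell receptor, was 2.70-fold lower, with both of its probe sets past 2-fold. Ccnyl1, 2900026A02Rik and Ces5a were 2.21-fold, 2.18-fold and 2.13-fold lower. Stra6, Ube2v2, Pde3b and Chchd5 completed the 12 lowest genes, at 1.96-fold, 1.89-fold, 1.83-fold and 1.75-fold lower. The other probe set of 2900026A02Rik had a log2 ratio of -0.42, and that of Chchd5 -0.034.

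**Figure D1:**
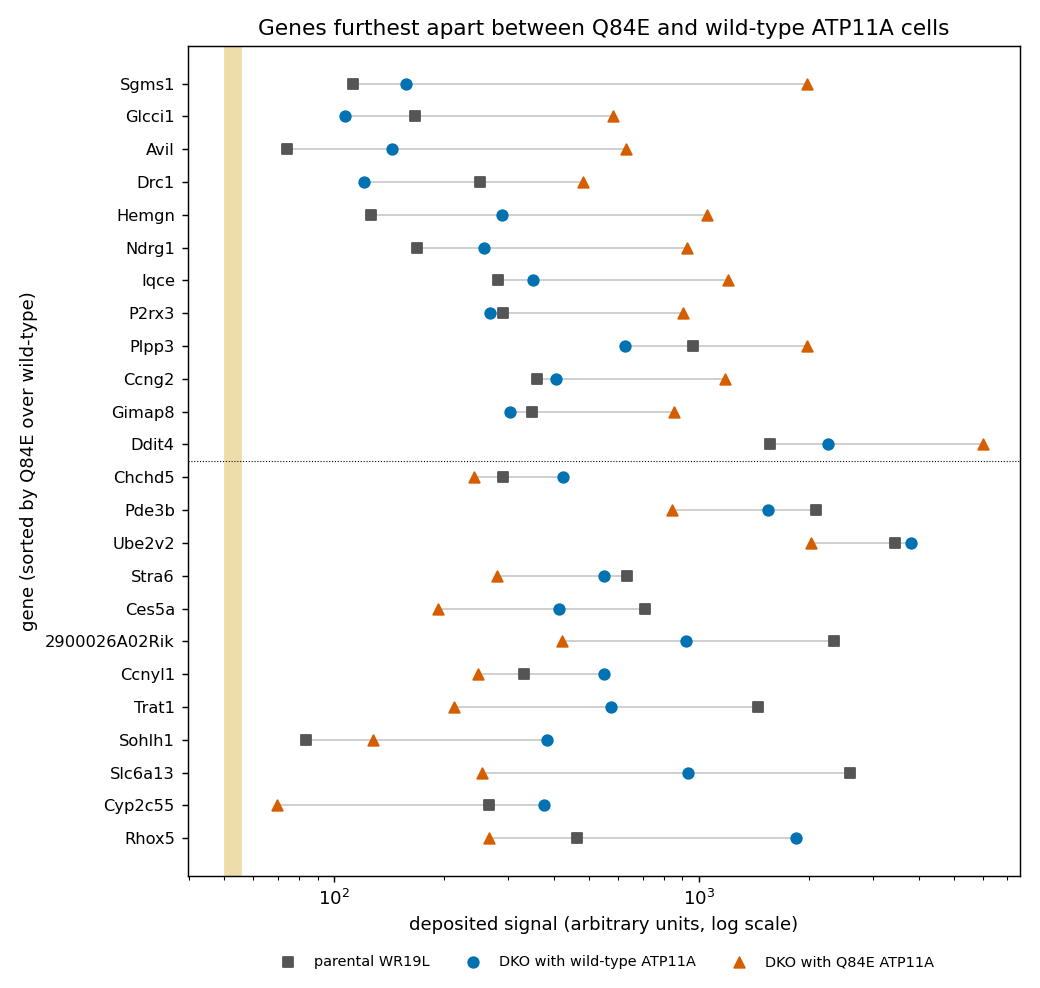
Deposited signal on a log axis of the 12 genes with the highest and the 12 with the lowest ratio of Q84E over wild-type ATP11A, with 1 array per group, squares for parental cells, circles for wild-type ATP11A and triangles for Q84E ATP11A; the shaded band spans the floors of 50.3 to 55.5, and there are no error bars. Sgms1 lies at 157 and 1977 on the wild-type and Q84E arrays, and Rhox5 at 1845 and 266.

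Among genes of sphingomyelin and ceramide synthesis, Sgms1 was the only 1 of 16 measured members past 2-fold by its brightest probe set. Levels under the floor were set to the floor here, and that of Degs2 was 10.0 with wild-type ATP11A. Sgms1 had 3 of 4 probe sets at least 2-fold higher with Q84E, at log2 ratios of 3.22, 3.66 and 4.32, and the remaining probe set had a log2 ratio of 0.33 at signals of 87.0 and 109.6. The next members were Degs2 at 0.43, which is a bound, Sptlc1, a subunit of serine palmitoyltransferase, at 0.32, with 1 of its 4 probe sets past 2-fold at 1.24, and Ugcg, glucosylceramide synthase, at 0.25. The median log2 ratio of the list was 0.070, at percentile 75.2 among 10000 random lists of the same size matched on level. Phosphatidylcholine synthesis had a median of 0.20 over 17 genes, at percentile 98.3, with 12 members above 0. Dgka, a diacylglycerol kinase, was 2.03-fold higher, and Lpin1, a phosphatidate phosphatase, was 1.94-fold higher. The choline transporter-like gene Slc44a2 was 1.53-fold higher.

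**Figure D2:**
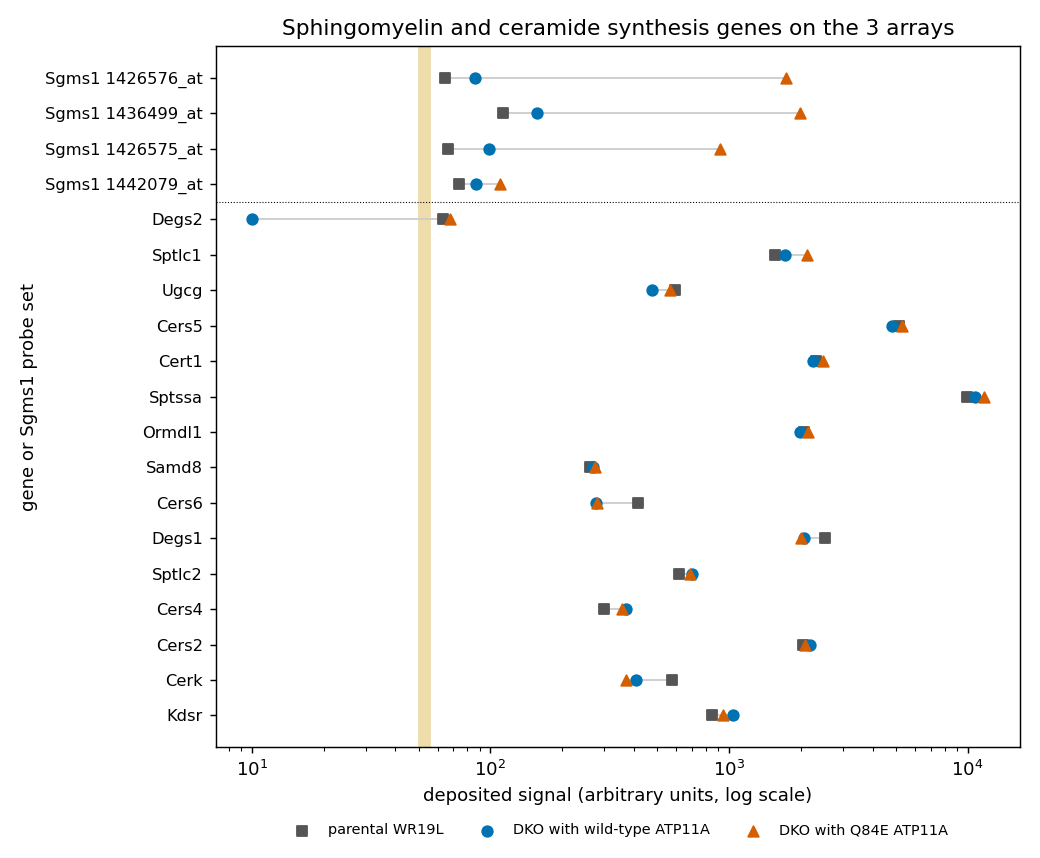
Deposited signal on a log axis of the 4 Sgms1 probe sets, above the dotted line, and of the other measured genes of sphingomyelin and ceramide synthesis, with 1 array per group, the same symbols for the 3 arrays and a shaded band for the floors of 50.3 to 55.5. With levels under the floor set to the floor, only Sgms1 passes 2-fold between Q84E and wild-type ATP11A by the probe set that represents each gene. Of its 4 probe sets, 3 do. The signals are drawn without the floor, so Degs2 lies at 10.0 with wild-type and 68.0 with Q84E ATP11A, and its ratio is a bound.

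Of the 35 gene lists that had enough measured members, 14 lay outside the central 95% of matched random lists for Q84E over wild-type. By chance 1.75 would do so if the genes within a list varied independently of each other. That was not tested, so 1.75 is not a calibrated limit for lists of related genes. Lists can also share members and are then not separate results. Lpcat3, at 0.20, was in the LXR and phosphatidylcholine lists and lay at the middle of both, and Scd1 was in the LXR and fatty acid lists. Cholesterol synthesis had a median log2 ratio of 0.17 over 21 genes, with 18 above 0 and none past 2-fold, at percentile 99.98. Its largest values belonged to Tm7sf2 at 0.47, Dhcr7 at 0.41, Srebf2, the master regulator of the pathway, at 0.33 and Pmvk at 0.33. Fatty acid synthesis and desaturation had a median of 0.15 at percentile 99.55, with Acaca, acetyl-CoA carboxylase 1, at 0.43, although its other probe set had -0.40. LXR and cholesterol efflux genes had a median of 0.20 at percentile 97.55, with Gramd1b at 0.61 and Apoe at -0.91, and the list fell back inside the central 95% under 8 of 11 alternatives. The T cell receptor complex and its signalling genes had a median of 0.36 at percentile 99.99, with 16 of 17 members above 0. The same list had -0.40 for wild-type over parental and 0.055 for Q84E over parental, so the wild-type array was the low one. Prkcq, a protein kinase C of T cells, was 2.24-fold higher, Rasgrp1 2.03-fold, the costimulatory receptor gene Cd28 1.97-fold and Cd2 1.93-fold. Of the 4 probe sets of Rasgrp1, 2 were past 2-fold, 1 of them by a bound, and 1 lay under the floor on both arrays, and the other probe set of Cd28 had a log2 ratio of 0.27. The early T cell and thymocyte list had a median of 0.18 at percentile 97.8, with Dntt at 0.97, its 3 probe sets between -0.30 and 1.46, and Tox at 0.82, and fell back inside under 4 of 11 alternatives. The list of T cell effector genes had a median of -0.51 over 6 genes, at percentile 0.070, with Gzma, granzyme A, 2.64-fold lower. Of its 20 genes with a probe set, 6 reached the 50th percentile on the wild-type array and 4 on the Q84E array, and none reached the 75th on either. Members could thus pass the filter through the wild-type array, which can lower this median, and the floor set the sign of Il17a.

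Genes of the integrated stress response downstream of ATF4 had a median log2 ratio of 0.15 at percentile 99.98, with 18 of 21 members above 0. Its largest members besides Ddit4 were Sesn2 at 0.82, the glutathione-degrading enzyme gene Chac1 at 0.68 and Ddit3, which encodes CHOP, at -0.71. Genes of glycolysis and the hypoxia response had a median of 0.14 at percentile 99.75, with 17 of 22 members above 0 and 5 below. Among those above, Ndrg1 and Ankrd37 were past 2-fold and Bnip3 was 1.73-fold higher. Targets of p53 had a median of 0.22 at percentile 97.53, with Btg2 at 0.75 and Mdm2 at 0.55, and fell back inside under 5 of 11 alternatives. Targets of MYC and ribosome biogenesis genes had a median of -0.11, with 20 of 22 members below 0, at percentile 0.29. Its lowest members were Ddx21 at -0.36 and Polr1b at -0.24. The cytosolic ribosomal protein list had a median of 0.095 at percentile 99.5, which became 0.012 with quantile normalization, at percentile 69.1. Genes of G2 and mitosis had a median of 0.053 at percentile 98.3, with Nusap1 at 0.44 and Mki67 at 0.43. The antigen presentation list had a median of 0.17 at percentile 98.0, with 7 of 13 members above 0. It was inside the central 95% under 8 of 11 alternatives, and its sign turned to -0.044 without the less specific probe sets. Of the lists outside without a count given above, ribosomal proteins fell back inside under 4 of 11 alternatives. Fatty acid synthesis, G2 and mitosis, and glycolysis and hypoxia did so under 2 of 11, phosphatidylcholine synthesis and the integrated stress response under 1 of 11, T cell effector genes under 1 of 9, and cholesterol synthesis, the T cell receptor list and MYC targets under 0. Among the other lists, the flippase list had a median of 0.14 at percentile 76.9. The median of the 9 phospholipid scramblase genes fell on Plscr4, which lay under the floor on both arrays, so it is set by the floors and no value is given, and Atg9a was at 0.88 and Xkr8 at 0.85.

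**Figure D3:**
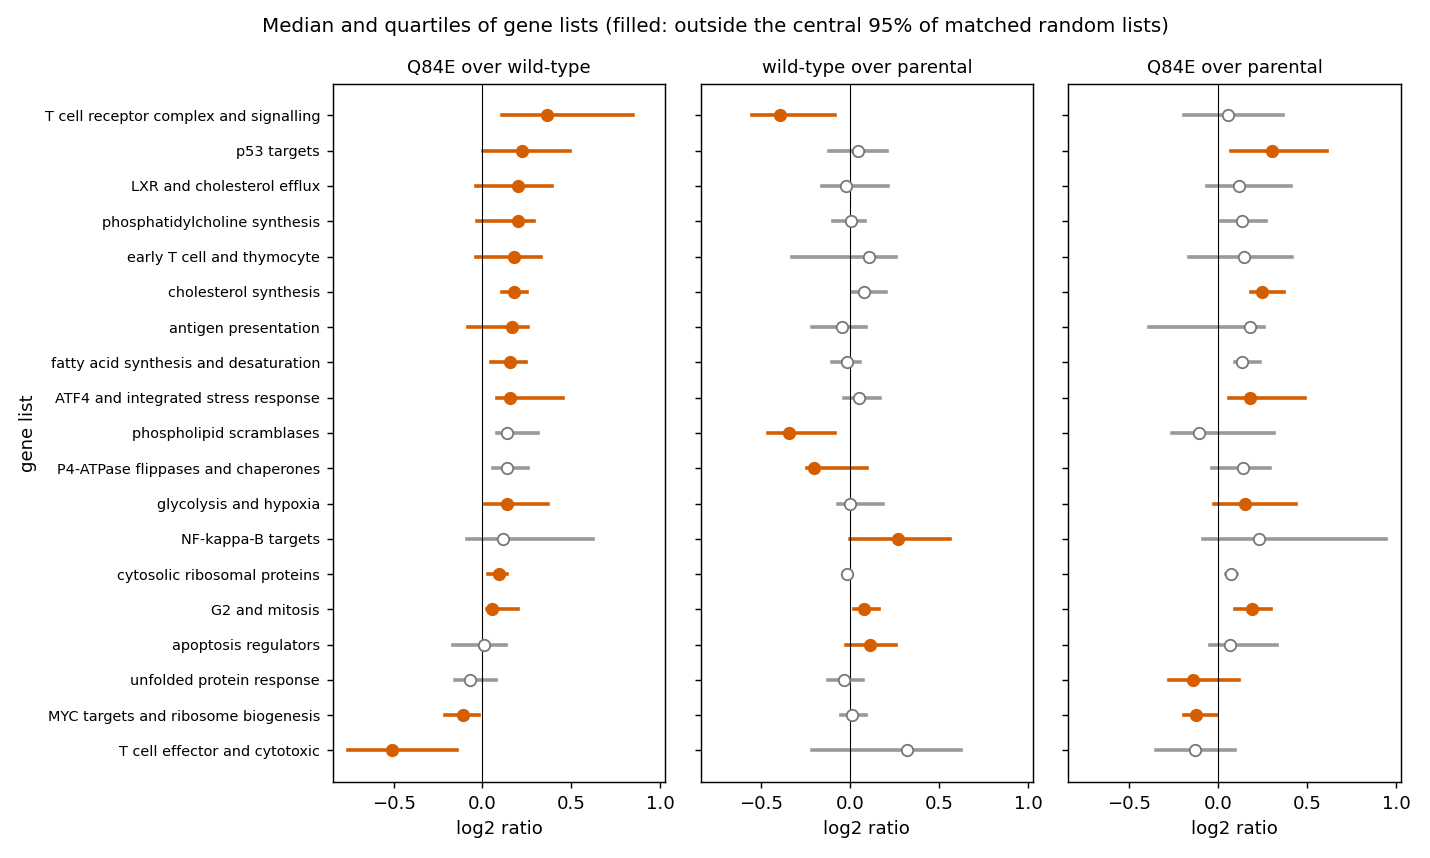
Median log2 ratio, as circles, and quartiles, as bars, over the members of each gene list in the 3 comparisons, for the lists outside the central 95% of matched random lists in at least 1 comparison; filled circles mark the comparisons in which that was so. The T cell receptor list has a median of 0.36 for Q84E over wild-type and -0.40 for wild-type over parental. Some medians drawn rest at least in part on genes under the floor on both arrays and are not measured values. They are those of scramblases for Q84E over wild-type, LXR for wild-type over parental and early T cell genes for Q84E over parental.

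The comparison of wild-type ATP11A cells with parental cells asked which genes differ between the DKO line with wild-type ATP11A and the parental line. At least 2-fold higher levels were found for 65 genes and lower levels for 103, of which 26 and 29 are bounds, and simulated unchanged genes passed 26.6 times on average and at most 40 times. The gene furthest apart was Ankrd33b, at least 48.6-fold higher in wild-type ATP11A cells, with a signal of 2448 against a parental signal under the floor, seen in 1 of 3 probe sets. Sohlh1 was 4.57-fold higher, Ccdc112 4.42-fold, Rhox5 3.99-fold, Dusp4, a phosphatase of MAP kinases, 3.84-fold, and Acbd3, a Golgi protein, 3.80-fold with all 4 probe sets past 2-fold. Fermt3, which encodes the integrin activator kindlin-3, was 3.42-fold higher with 3 of 4 probe sets. Shisa5, Wdr70, Tle6, Ccdc18 and Tspan32 were 2.94-fold, 2.75-fold, 2.47-fold, 2.34-fold and 2.13-fold higher. The other probe set of Wdr70 had a log2 ratio of 0.27 and that of Tspan32 0.078, at signals well above the floor, and the others of Ccdc18 had 0.014 and 0.16, which are bounds.

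The lowest gene of wild-type over parental was H2-D1, a class I histocompatibility gene, at 16.3-fold lower. That value came from a probe set of the kind that shares sequence with related genes, and without such probe sets its log2 ratio was -0.039, so the value is uncertain among its paralogs. Lrrc8e, a subunit of volume-regulated anion channels, was at least 11.6-fold lower and Ppp4r1, a regulatory subunit of protein phosphatase 4, at least 8.32-fold lower. Itln1 was 7.49-fold lower, Crispld2 5.72-fold by a less specific probe set, against log2 ratios of -1.37 and -0.85 for its other probe sets, Cpeb1, a regulator of mRNA translation, 4.48-fold, and Icam4 4.12-fold. Tuba8, an alpha-tubulin, was 3.79-fold lower, Fam163b 3.68-fold, Pde2a, a phosphodiesterase of cyclic nucleotides, 3.54-fold, P2ry10 3.43-fold and Rtl8c 3.40-fold. The other probe set of Fam163b had a log2 ratio of -0.91, which is a bound, and those of Pde2a had -1.76 and -0.46.

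For wild-type over parental, 6 of the 35 lists lay outside the central 95% of matched random lists. The T cell receptor list had a median log2 ratio of -0.40, with 15 of 17 members below 0, at percentile 0, meaning that none of the 10000 random lists was lower. Cd8b1 was 2.63-fold lower, and Cd2, Cd8a and Cd3d had log2 ratios of -0.89, -0.72 and -0.69. The scramblase list had a median of -0.34 at percentile 0, with Atg9a at -0.57 and Xkr8, a scramblase cleaved by caspases, at -0.46, and it turned to 0.061 when all probe sets of a gene were averaged. The flippase list had a median of -0.20 at percentile 0.77, with Atp11a the furthest apart, and fell back inside under 4 of 11 alternatives. Targets of NF-kappa-B had a median of 0.27 at percentile 98.5, with Nfkb2 2.87-fold higher by 1 of its 2 probe sets, and fell back inside under 3 of 11 alternatives. The apoptosis list had a median of 0.11 at percentile 98.0, with Bad at 0.62, against -0.26 by its other probe set, and Fas at 0.40, and fell back inside under 6 of 11 alternatives. Genes of G2 and mitosis had a median of 0.077 at percentile 99.5. That list and the scramblase list each lost their place outside under 2 of 11 alternatives, and the T cell receptor list under 0. Cholesterol synthesis had a median of 0.076 at percentile 96.6.

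The comparison of Q84E cells with parental cells gave 189 genes at least 2-fold higher and 92 lower, of which 54 and 25 are bounds, against 27.2 on average and at most 38 in simulations of unchanged genes. With quantile normalization the split was 119 higher and 118 lower, and with a common median it was 143 higher and 105 lower. Ankrd33b was at least 24.6-fold higher, by 1 of 3 probe sets, and Sgms1 was 17.5-fold higher. Avil was 8.52-fold higher, Hemgn 8.30-fold, Dusp4 7.77-fold, Ndrg1 5.49-fold, Acbd3 4.82-fold, Fermt3 4.74-fold, Iqce 4.29-fold, Ddit4 3.84-fold, Ccdc112 3.70-fold and Vsir, which encodes the checkpoint receptor VISTA, 3.55-fold. Among the lowest genes, Lrrc8e was at least 10.6-fold lower, Slc6a13 10.2-fold, Ppp4r1 at least 7.57-fold, Itln1 7.55-fold, Trat1 6.80-fold, Gzma 6.77-fold, Tuba8 6.22-fold and 2900026A02Rik 5.56-fold. Crispld2, Pde2a, Rtl8c and Ces5a were 4.51-fold, 4.44-fold, 3.79-fold and 3.68-fold lower. The other probe sets of Crispld2 had log2 ratios of -1.46 and -1.14, that of Tuba8 had -1.46, that of Vsir had 0.77 and those of Iqce had 1.40 and 0.60, while the probe sets of Pde2a ranged from -2.43 to -0.996. For Ces5a the log2 ratio was 0.098 when all of its probe sets were averaged, and for H2-D1, at 13.1-fold lower, the log2 ratio was -0.51 without the less specific probe sets.

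For Q84E over parental, 7 of the 35 lists lay outside the central 95% of matched random lists. Cholesterol synthesis had a median log2 ratio of 0.25, with 19 of 21 members above 0, at percentile 100, and Srebf2 at 0.60, Stard4 at 0.58, Insig1 at 0.45 and Fdft1 at 0.39 were its largest members. The integrated stress response list had a median of 0.18, with 20 of 21 members above 0, at percentile 100, and Nupr1 was 2.90-fold higher. Genes of G2 and mitosis had a median of 0.19 at percentile 100, with Nusap1 at 0.73 and Cenpf at 0.55. Targets of p53 had a median of 0.30 at percentile 99.3, with Trp53inp1 at 0.80, Bbc3 at 0.78 and Perp at -1.15. Glycolysis and hypoxia genes had a median of 0.15 at percentile 99.5, with 16 of 22 members above 0 and 6 below, Bnip3 at 0.97 and Vegfa at 0.57. Targets of MYC had a median of -0.13 at percentile 0.33, with Pes1 at -0.43 and Odc1 at -0.31. The unfolded protein response list had a median of -0.14 at percentile 0.30, with Sdf2l1 at -0.44 and Dnajc3 at -0.35, the latter inside a stretch of neighbouring genes that were lower in both DKO lines than in parental cells. Of these 7 lists, glycolysis and hypoxia and the unfolded protein response fell back inside under 2 of 11 alternatives, the integrated stress response, G2 and mitosis and p53 targets under 1, and cholesterol synthesis and MYC targets under 0. The T cell receptor list had a median of 0.055 at percentile 62.9.

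The 3 comparisons share arrays, so each array was also set against both others at once. On the parental array 86 genes were at least 2-fold apart from both other arrays in the same direction, 53 higher and 33 lower. On the Q84E array 63 genes were, 50 higher and 13 lower, and on the wild-type ATP11A array 26 were, 10 higher and 16 lower. The split into higher and lower was not repeated with other scalings, on which the excess of higher genes in the comparisons of Q84E depended. Simulations of unchanged genes gave 2.03 to 2.35 genes apart from both other arrays on average and at most 7. The genes named next were taken only from those that reached the 75th percentile of signal in both comparisons of an array, and they need not be 2-fold apart. Within that limit, Sgms1, Hemgn, Avil, Ndrg1 and Glcci1 were higher on the Q84E array than on both others by the widest margin, and Slc6a13, Trat1, 2900026A02Rik, Ces5a and Stra6 were lower, Stra6 by less than 2-fold. Cyp2c55, which lies under that limit against parental cells, had log2 ratios of -2.43 and -1.93 over wild-type and parental cells. On the wild-type array Rhox5, Sohlh1, Ankrd33b, Tsc22d1 and Ccnyl1 were the highest within the limit, and Ccr9, Pdcd1, Tmem237, Cd2 and St3gal6 the lowest. Of these 10 genes only Rhox5 and Sohlh1 were at least 2-fold apart from both others. The signal of Pdcd1, which encodes the inhibitory receptor PD-1, was 1288, 593 and 1171 in parental, wild-type ATP11A and Q84E cells, and that of the chemokine receptor gene Ccr9 was 814, 309 and 599. On the parental array H2-D1, Lrrc8e, Ppp4r1, Itln1 and Crispld2 were higher, and Ankrd33b, Ccdc112, Dusp4, Acbd3 and Fermt3 lower, than on both others.

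The levels of cell type markers were compared among the 3 arrays. Genes of the T cell receptor list had a median level at the 84.1, 81.9 and 83.5 percentile of all probe sets in parental, wild-type ATP11A and Q84E cells. B cell markers had a median level at the 56.2, 41.1 and 51.1 percentile, with Pou2af1 the only one above the 75th. Myeloid markers had a median at the 36.2, 33.96 and 40.3 percentile, and none lay above the 75th. Erythroid and megakaryocyte markers had medians at the 49.9, 46.9 and 26.4 percentile, and fibroblast and stromal markers at the 44.4, 46.5 and 41.1 percentile, where Vim, which T cells express too, was the highest. Ratios of 3' to 5' control probe sets were 0.72 for Gapdh on each array and 1.24 to 1.27 for beta-actin, and for the transferrin receptor they were 2.74, 2.96 and 3.27 in parental, wild-type ATP11A and Q84E cells.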

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

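All tests on Sgms1, and those on FOXO targets other than the repeat with quantile normalization, were chosen only after the result was seen.

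In 4 named genes the wild-type ATP11A and Q84E arrays lay on opposite sides of the parental array, each by at least 1.5-fold. The log2 ratio over parental cells was -1.06 for Drc1 in wild-type ATP11A cells and 0.93 in Q84E cells. For Glcci1 it was -0.64 and 1.80 by its brightest probe set, while another probe set of Glcci1 gave 0.40 and 1.84, on the same side. For Plpp3 it was -0.61 and 1.04. For Rhox5 it was 1.998 in wild-type ATP11A cells and -0.80 in Q84E cells. With 1 array per group the difference was not tested.

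Probe sets without a single gene name were outside the comparisons. Of those above the 75th percentile, 5 were at least 2-fold above the parental array in wild-type ATP11A cells and 7 in Q84E cells, and 4 and 8 were at least 2-fold below it.

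Sgms1 was 12.6-fold higher with Q84E than with wild-type ATP11A. A single faulty or cross-hybridising probe set would leave at most 1 probe set past 2-fold, and 3 of the 4 Sgms1 probe sets passed it. Scaling between arrays as the whole cause would bring the log2 ratio under 1 after quantile normalization, and it was 3.62. A difference between the transduced cell populations other than the mutant protein, such as a clone or a site of integration, cannot be told apart from the mutant, because there was 1 array per group. A link between Q84E ATP11A and Sgms1 may therefore stand only as a hypothesis, which independently made lines would test.

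FOXO transcription factors are kept out of the nucleus by growth factor signalling through AKT, and a list of 31 of their targets was written after the genes with the highest ratios had been seen. The median log2 ratio of its 28 measured genes for Q84E over wild-type was 0.30, at percentile 100 of matched random lists, and at percentile 99.98 after quantile normalization. The random lists were matched on level, so an array-wide upward shift of mid-level genes would be in them too. The repeat could therefore not test such a shift. In both settings the list lay above genes of like level. The list holds 4 genes that had been seen before or were added later, so it is not independent evidence, and without them the median was 0.20 at percentile 98.9, with 22 of 25 genes above 0, or 21 of 24 without Il7r, which lay under the floor on both arrays. For wild-type over parental cells the full list had a median of 0.12 at percentile 97.6, and without those genes it lay at percentile 90.6, inside the central 95%. Lower growth signalling may account for the pattern only as a hypothesis, since signalling was not measured here, and culture state on the day of harvest, such as density or use of the medium, cannot be told apart from it with 1 array per group.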

How the results depend on the processing

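No paired analysis was possible because each group had 1 array and the labels share no replicate numbers. Of 350 list medians under the alternatives, 286 kept their direction and side of the central 95%, 60 fell back inside it, 2 moved outside and 2 changed sign. Of 90 counts, 44 stayed within 1.5 times the value reported and 46 did not. Of 3816 values of named genes, 3591 were the same, 183 moved, 40 no longer passed 2-fold and 2 changed sign. Cholesterol synthesis with Q84E over both other lines, the T cell receptor list for Q84E over wild-type and wild-type over parental, and MYC targets with Q84E over both others stayed outside the central 95% under all 11 alternatives run. The values of each of these lists share an array and are not separate results. It is the wild-type array for the T cell receptor list and the Q84E array for the others. Counts moved most with no floor. Each setting of the floor also changed the filter on genes, which left 13885 genes with the 40th percentile, 8581 with the 65th and 18194 with no floor, against 11596, so the effects of floor and filter on the counts were not separated. The T cell effector list had too few members for a value with the floor at the 65th percentile and with genes above the floor on both arrays. For the list values below the cause was not tested, except where the setting itself sets it. A common floor and the restriction to genes above the floor on both arrays were chosen after seeing the data.

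Counts are given as higher and lower, for Q84E over wild-type, wild-type over parental and Q84E over parental. With the floor at the 40th percentile they were 306 and 128, 191 and 236, and 380 and 180, and 164, 82 and 168 genes stood apart on the parental, wild-type and Q84E arrays. With the floor at the 65th percentile they were 30 and 10, 19 and 45, and 63 and 49, with 45, 4 and 25 apart. With no floor they were 2060 and 1802, 1912 and 1950, and 2141 and 1922, with 1936, 1805 and 1896 apart. At 1.5-fold they were 670 and 229, 407 and 413, and 853 and 341, and at 3-fold 15 and 6, 15 and 23, and 38 and 28. Quantile normalization gave 68 and 64 for Q84E over wild-type and 119 higher for Q84E over parental. The mean of a gene's probe sets gave 73 lower for Q84E over wild-type, 102 higher for wild-type over parental and 47 apart on the wild-type array, and genes above the floor on both arrays gave 39 higher for wild-type over parental.

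The list medians that fell back inside the central 95% are for Q84E over wild-type unless said otherwise. With genes above the floor on both arrays they were LXR at 0.14, antigen presentation at 0.068 and G2 and mitosis at 0.053. With a common floor they were LXR at 0.20, p53 targets at 0.22 and antigen presentation at 0.10, and with a common median LXR at 0.15. With the floor at the 40th percentile they were LXR at 0.20, early T cell genes at 0.13 and, for wild-type over parental, apoptosis at 0.086. With the floor at the 65th percentile they were p53 targets at 0.22 and antigen presentation at 0.15. With no floor they were LXR at 0.21, early T cell genes at 0.19 and T cell effector genes at -0.32, and for wild-type over parental flippases at -0.12, scramblases at -0.084, NF-kappa-B targets at 0.27 and apoptosis at 0.086. With quantile normalization they were antigen presentation at 0.12, early T cell genes at 0.12 and ribosomal proteins at 0.012.

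With the mean of a gene's probe sets, LXR was at 0.20, fatty acid synthesis at 0.090, phosphatidylcholine synthesis at 0.20, p53 targets at 0.17, antigen presentation at 0.037 and glycolysis and hypoxia at 0.064, and for Q84E over parental glycolysis and hypoxia was at 0.082 and the unfolded protein response at -0.085. For wild-type over parental, flippases were at -0.16, NF-kappa-B targets at 0.078, G2 and mitosis at 0.033 and apoptosis at 0.083, and scramblases turned to 0.061. In this setting Ces5a turned to 0.098 for Q84E over parental, and Atp11a had log2 ratios of 0.46, -1.97 and -1.51 for Q84E over wild-type, wild-type over parental and Q84E over parental. The Atp11a averages take in its dimmer probe set, under the floor at 16.3 with wild-type and 31.7 with Q84E ATP11A, so they are not measured ratios. The brighter probe set had -0.051 for Q84E over wild-type. With the mean of a list, LXR was at 0.097, p53 targets at 0.23, antigen presentation at 0.089, early T cell genes at 0.20 and ribosomal proteins at 0.067, for Q84E over parental p53 targets at 0.24 and the unfolded protein response at -0.083, and for wild-type over parental flippases at -0.17 and apoptosis at 0.14. Sphingomyelin and ceramide synthesis moved outside the central 95% by its mean, at 0.30 for Q84E over wild-type and 0.26 for Q84E over parental, since a mean takes in the ratio of Sgms1.

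Without probe sets ending in _x_at or _s_at, LXR was at 0.20, p53 targets at 0.22 and ribosomal proteins at 0.072, and for wild-type over parental flippases were at -0.12, NF-kappa-B targets at 0.11 and apoptosis at 0.11. Antigen presentation turned to -0.044, and Nfkb2 to -0.36 for Q84E over parental. Against random lists not matched on level, values that stay as they are fell back inside for fatty acid synthesis at 0.15, the integrated stress response at 0.15 and, for Q84E over parental, 0.18, antigen presentation at 0.17 and ribosomal proteins at 0.095. The same held for G2 and mitosis at 0.053, for wild-type over parental at 0.077 and for Q84E over parental at 0.19, for glycolysis and hypoxia at 0.14 and, for Q84E over parental, 0.15, and for apoptosis at 0.11 for wild-type over parental.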

Other observations

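The tests on windows of 20 and 12 genes, both tests on the longest unbroken run, and the shuffles for the copy loss were chosen only after the result for windows of 50 genes was seen.

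Of the 28 measured FOXO targets, 22 had their highest signal in Q84E cells, 4 in parental and 2 in wild-type ATP11A cells, by any margin, and the members named here were picked after their values were seen. The share of all genes highest in Q84E cells was not counted. Over all genes the median log2 ratio of Q84E was 0.046 over wild-type and 0.068 over parental cells. The 28 also include genes seen before or added later, Foxo3 among them. Foxo3, a FOXO factor itself, had signals of 255, 346 and 818 in parental, wild-type ATP11A and Q84E cells, and Txnip, an inhibitor of thioredoxin, had 304, 441 and 808. Btg1, an antiproliferative gene, had 478, 696 and 1051, and Bcl6, a transcriptional repressor, 590, 799 and 1055. The 4 that were highest in parental cells were Il7r, which encodes a subunit of the interleukin 7 receptor, with 186 and levels under the floor in both DKO lines by its brightest probe set, Cdkn1b with 988, 870 and 958, Insr with 339, 290 and 330, and Tnfsf10 with 86.4, 68.2 and 65.3. Klf2 and Cited2 were highest in wild-type ATP11A cells.

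A stretch of neighbouring genes was lower in both DKO lines than in parental cells, in the gene order of the GRCm38.p6 annotation and over 6881 genes that reached the 75th percentile on an array. The longest unbroken run of genes on 1 side of 0 in both lines held 25 genes, from Sugt1 to Tmtc4. Its median log2 ratio was -0.74 for wild-type over parental, -0.80 for Q84E over parental and -0.061 for Q84E over wild-type. Of the 25 genes, 3 and 8 were at least 2-fold lower in wild-type ATP11A and Q84E cells. Dock9, a guanine nucleotide exchange factor, had -1.24 and -1.62, Stk24, a protein kinase, -1.17 and -1.31, and Ipo5, an importin, -0.99 and -1.19, while Sugt1 at the edge had -0.10 and -0.13. The 30 genes before the run had medians of -0.052 and 0.047. Windows of 20 genes gave -0.77 and -0.85 at the extreme, and windows of 12 genes -0.83 and -1.02, with 0 of 1000 shuffled gene orders as far from 0.

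In windows of 50 genes, the most extreme for Q84E over parental ran from Fndc3a to Ggact with a median of -0.31, and the chance order of genes is argued against by 0 of 1000 shuffles as extreme, the highest at 0.23, and by 0 of 1000 with a run of 25, the longest at 17. A few strongly lower genes as the whole cause were left open by the planned test on this window, which reaches beyond the run, as 61.9% of its genes that were not 2-fold lower lay below 0, between the bounds set before; in the run itself the values argue against it, since its 17 genes not 2-fold lower in Q84E cells had a median of -0.73, against -0.17 for the other genes below 0 in both lines and a probe set error of 0.23 (SD). Loss of a copy of the segment, already present in the wild-type ATP11A line, required a window median for wild-type over parental at least 50% as far below 0 as the Q84E value. It was -0.17, or 55.1% of the Q84E value. But both ratios use the parental array, and 8.20% of shuffles that kept the ratios of a gene together reached 50% or more too. Shuffled windows were weaker than this one, as 0 of 1000 above were as extreme, so that share is only a rough guide. With 1 parental array, a copy lost in cells from which both DKO lines came cannot be told apart from a higher level in the parental cells alone. DNA was not measured here, shared silencing of the stretch was not tested, and the window lengths and the run rule were tried on the same 3 arrays.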
